A study of Homo sapiens with 6 samples.

How the data were processed

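Messenger RNA abundance was measured by RNA sequencing in 6 libraries labelled as the human breast cancer line MCF7, an estrogen receptor positive luminal line. Per the labels, 2 libraries came from control cells and 2 each from lines B1 and C3, in which TDRD3 was knocked out with different guide RNAs. The labels do not say which guide was used for which line. Replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

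The deposited values were whole-number read counts per gene symbol, not normalized. Per the submitters' processing notes, the tools named were Trimmomatic 0.39, fastp 0.20.1, STAR 2.7.4a, featureCounts and edgeR 3.28.1, and the build was hg19. The version of featureCounts, the annotation and the strand setting were not given in the sources used here. Reads of near-identical or overlapping genes could have been split or dropped in that step, so values of TARP, HLA, metallothionein, histone, ribosomal protein, PRAME and zinc finger genes are uncertain, as is EMX2OS, an antisense gene. Each file held 23354 symbols and no summary line.

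Total counts ran from 17128386 to 17612664 per library, and 1 count stood for 0.0535 to 0.0648 CPM, a unit of counts scaled by library size. Counts within a pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.59 in the control, 1.33 in B1 and 2.39 in C3, and no pair of files was identical. Intervals and floors cover counting error only.

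Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group, which left 15124 genes, and libraries were scaled by the trimmed mean of M values (TMM). All 6 libraries entered 1 quasi-likelihood fit with 1 coefficient per group, so that the pairs share an estimate of the spread. The common biological coefficient of variation was 2.48%. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. CPM values use the TMM-scaled library sizes, and the ± after a log2 fold change is its standard error, taken from the fold change and its F statistic. Where a group had 0 counts over its 2 libraries, the fold is a bound set against 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% counting interval. No fold is given where both groups had at most 3 counts.

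The 25 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The rule for the genes named was fixed then too. It took TDRD3 and DHX9, the 8 largest shared changes in each direction by the smaller change of the 2 lines, the 5 largest further changes per direction in each line, the 4 largest per direction between the lines, and up to 3 called members per list, all with an adjusted p below 0.05 and a mean of at least 2 CPM. Symbols of uncharacterised, microRNA, small RNA and -AS genes were left out of the ranking. TOP3B, MTAP, CDKN2A and the line markers PAX2, INA, CDH2, VIM, NES and NEFH were named outside that rule. TOP3B was chosen after its values were seen, and the others come from marker lists written after the largest changes had been seen but before the values of these genes were looked at.

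The scripts were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes among 15124 genes. Of each 50, the test recovered 18 at 1.2-fold, 40 at 1.5-fold, 45 at 2-fold, 49 at 4-fold for B1 against the control. It recovered 26 at 1.2-fold, 41 at 1.5-fold, 45 at 2-fold, 48 at 4-fold for C3 against the control, 27 at 1.2-fold, 42 at 1.5-fold, 45 at 2-fold, 49 at 4-fold for the mean of the lines, and 23 at 1.2-fold, 41 at 1.5-fold, 46 at 2-fold, 49 at 4-fold for B1 against C3. Among unchanged genes it called 3 of 14649, 7 of 14663, 10 of 14650 and 3 of 14649 in these comparisons. Chance values for comparisons that share the control libraries came from 20 simulations without any change.

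Alternatives were DESeq2 size factors, total-count scaling, no filter beyond 1 count, a filter of 1 CPM in 2 libraries, leaving out each library, the replicate number as a block, DESeq2 1.42.0, a minimum fold of 1.5, fits of only the groups compared, and the estimated correlation. Leaving out a library leaves its group with 1 library, which is assumed to vary like the others. Neighbouring genes were looked up by symbol in the NCBI RefSeq table of GRCh38.p14, where 14967 of the 15124 symbols matched, 691 of them by an older symbol. That build differs from hg19, so no coordinates are given. Other splits of the samples were not counted because each group has 2 libraries.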

Results

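RNA sequencing counts of 6 libraries labelled MCF7 were compared, 2 from control cells and 2 from each of the lines B1 and C3, which carry the label of TDRD3 knockouts made with different guide RNAs. TDRD3 is a Tudor domain protein that binds methylated arginines and partners with the topoisomerase TOP3B, and the title of the series places it with the helicase DHX9 and with R-loops, which are RNA:DNA hybrids. Between 17128386 and 17612664 counts were assigned per library. Counts were found for 16827 and 16866 genes in the control libraries and for 17367 to 17509 in the other 4. The first principal component held 95.1% of the variance and separated the control libraries from the other 4, and the second held 3.13% and separated B1 from C3.

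The targeted gene was lower in the 4 libraries labelled as knockouts but was not absent. TDRD3 had 449 and 411 counts in the control libraries, 168 and 147 in B1 and 94 and 98 in C3. These correspond to 27.8 ± 1.65 CPM in the control, 8.43 ± 0.793 CPM in B1 and 5.29 ± 0.0567 CPM in C3 (mean ± SD, n = 2). The log2 fold change was -1.72 ± 0.10 in B1 and -2.39 ± 0.11 in C3 (edgeR quasi-likelihood test, adjusted p = 5.95e-25 and 2.88e-30). Gene counts do not show whether a remaining transcript carries a frameshift. Against the control 12954 of 15124 genes were called in B1 and 12904 in C3, so a lower TDRD3 alone does not show the edit. DHX9 was higher by 0.17 ± 0.034 in B1 and 0.26 ± 0.034 in C3 on the log2 scale, and TOP3B by 0.48 ± 0.06 and 0.68 ± 0.059. The size of these differences rests on the scaling: with total-count scaling DHX9 was higher by 0.41 and 0.48 and TOP3B by 0.72 and 0.89. With TMM scaling the differences of DHX9 and TOP3B were smaller than the median absolute log2 fold change of all genes, 0.83 in B1 and 0.84 in C3.

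**Figure D1:**
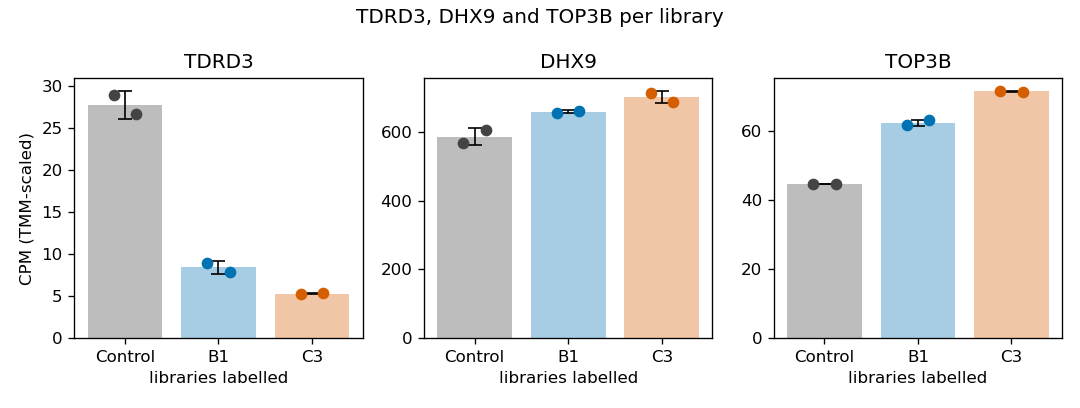
TMM-scaled CPM (vertical axes, linear from 0) of TDRD3, DHX9 and TOP3B in the libraries labelled Control, B1 and C3; points are libraries, bars the mean of 2 libraries and error bars the SD. TDRD3 lies at 27.8 CPM in the control, 8.43 CPM in B1 and 5.29 CPM in C3.

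The comparison of B1 with the control asks which transcripts differ in the first line. Transcripts typical of luminal breast epithelium were lower. KRT19, a keratin of luminal cells, fell from 665 ± 3.78 CPM in the control to 0 counts, at least 8284-fold lower, and TFF1, a secreted protein induced by estrogen, was at least 3939-fold lower. ESR1, the estrogen receptor, had 14515 counts over the control libraries and 2 over the B1 libraries, a ratio of 8764-fold with a counting interval of 2426 to 72374. The epithelial splicing factor ESRP1, the transcription factor GRHL2, the desmosomal PKP3 and the surface protein TACSTD2 had 0 counts in B1 and were at least 4012, 3113, 2143 and 1753-fold lower. TARP was at least 1522-fold lower, and it overlaps T cell receptor gamma sequence. Conversely PTPRD, a receptor phosphatase, had 0 counts in the control and 401 over the B1 libraries. FOXE1, GPR50, ZSCAN18 and BNC2 had 0 counts in the control and were at least 99.9, 88.6, 86.4 and 83.1-fold higher. In all, 6530 genes were higher and 6424 lower among 15124 tested, of which 3647 and 2869 differed by at least 2-fold. Total-count scaling moved the median log2 fold change of all genes from 0.018 to 0.26 in B1 and from 0.017 to 0.23 in C3, and gave 7857 higher and 5134 lower genes in B1.

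The same question was asked of C3, the other line. Against the control, 6534 genes were higher and 6370 lower, 3692 and 2969 of them by at least 2-fold. With total-count scaling 7754 were higher and 5199 lower. PRLR, the prolactin receptor, the melanosome transport gene MLPH, TSPYL5, SUSD3 and DSCAM had 0 counts in C3 and were at least 2554, 1989, 2185, 671 and 605-fold lower. The cationic amino acid transporter SLC7A3, the choline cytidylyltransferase PCYT1B, the retinoid-binding RBP7, the homeobox gene NKX2-4 and CCBE1 had 0 counts in the control and were at least 112, 94.3, 89.5, 83.8 and 83.2-fold higher. ESRP1 kept 4 counts over the C3 libraries (-11.42 ± 0.12 on the log2 scale), and GRHL2 kept 3, a ratio of 3025-fold with a counting interval of 1035 to 14670.

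Most differences from the control had the same direction in the lines. Genes without a count in the control and present in both lines included CHST2, a sulfotransferase (at least 173-fold higher in B1 and 169-fold in C3), the homeobox gene NKX6-1 (109.9 and 128), FOXN4 (118 and 107), ZNF649 (92.7 and 89.8), EMX2OS (117 and 88.6), the retinol carrier RBP1 (88.1 in B1, with 389 counts over the C3 libraries), SNPH (84.2 and 200.3) and the cadherin FAT3 (83.4 and 128). Besides KRT19, TFF1 and ESR1, the shared losses were led by LAD1, FAM111B, GGT6, ALDH3B2 and B3GALNT1, each with 0 counts in the 4 libraries and at least 1131, 905, 825, 703 and 664-fold lower in C3. In total 37 genes had at least 10 CPM in both control libraries and 0 counts in all 4 others, and 2 genes the reverse. Called in the same direction were 5862 genes higher and 5810 lower in both lines, where simulations without change gave 0 and independent lists would share 2821 and 2706, while 126 genes were called higher in B1 and lower in C3 and 136 the reverse. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.976 (simulated 0.543), with a covariance of 6.77 (simulated 0.0158). Part of the excess of shared calls over independent lists may come from the shared control libraries, since a split would leave 1 for each line. With total-count scaling 7146 genes were higher and 4628 lower in both lines. The mean of the lines differed from the control for 6675 higher and 6494 lower genes, or 7952 and 5273 with total-count scaling. Of the lists, 4 passed for the mean (camera): luminal markers, estrogen-induced genes, basal and mesenchymal markers and cholesterol synthesis, with adjusted p = 2.90e-14, 5.15e-10, 0.00526 and 0.0419; adjusted p = 0.073, 0.127, 0.271 and 0.345 with an estimated correlation. The cholesterol list did not pass for the mean with total-count scaling, without B1 replicate 2 or without C3 replicate 2, where 3 lists passed in each of the last pair, and without control replicate 1 there were 7.

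Lists of lineage markers differed from the control in both lines. All 23 luminal epithelial markers were lower in each line, with median log2 fold changes of -7.89 in B1 and -6.60 in C3 (camera, adjusted p = 9.89e-14 and 3.60e-15; adjusted p = 0.0638 and 0.0747 with an estimated correlation). Of 29 estrogen-induced genes 28 were lower and 1 higher in each line, among them the progesterone receptor PGR and TFF3, which had 0 counts in the 4 libraries (medians -2.71 and -3.08, adjusted p = 1.37e-09 and 1.95e-10; 0.0638 and 0.174 as adjusted p with an estimated correlation). Of 20 basal and mesenchymal markers 14 were higher in each line, with 4 lower in B1 and 3 in C3 (medians 3.39 and 3.85, the latter 3.78 with bounds for genes at 0 counts; adjusted p = 0.00684 and 0.0026; adjusted p = 0.28 and 0.236 with an estimated correlation). The mesenchymal transcription factors SNAI2, ZEB2 and TWIST1 rose by 7.62 ± 0.20, 7.60 ± 0.22 and 7.26 ± 0.26 on the log2 scale in B1 and by 8.08 ± 0.18, 7.50 ± 0.23 and 7.19 ± 0.26 in C3. Neurofilament genes rose as well, NEFL from 0.937 CPM to 73.8 and 109 CPM and NEFM from 1.87 to 91.6 and 176 CPM, as did the adhesion molecule NCAM1 (6.41 ± 0.17 and 6.25 ± 0.17). The neuronal list of 20 held 12 higher and 7 lower members in B1 and 13 and 6 in C3 (camera adjusted p = 0.167 and 0.147). MTAP and CDKN2A, which MCF7 is known to have lost by deletion, lay at 5.17 ± 0.441 and 2.39 ± 0.45 CPM in the control, at 109 ± 2.83 and 256 ± 1.73 CPM in B1 and at 107 ± 2.62 and 217 ± 0.641 CPM in C3. In the control libraries, 47 transcripts abundant in the other 4 libraries lay at a median of 1.23% of the level there.

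**Figure D2:**
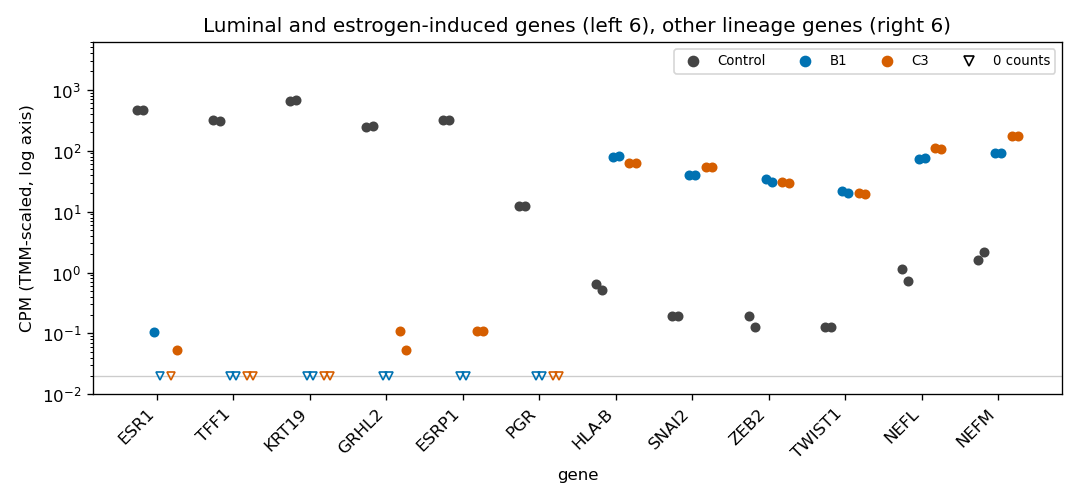
TMM-scaled CPM (vertical axis, log scale) of 12 genes (horizontal axis) in each of the 6 libraries, with colour for the label Control, B1 or C3 and open triangles on the bottom line for 0 counts. KRT19 lies near 665 CPM in the control and at 0 counts in the other 4 libraries, while SNAI2 lies at 0.194 CPM in the control, 39.6 in B1 and 54.4 in C3.

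Lists of other cell type markers, antigen presentation and cancer-testis genes did not pass the list test against the control with the settings used here, while single members differed. Of 9 fibroblast markers tested, 5 were higher in B1 and 8 in C3, with 1 lower in each (adjusted p = 0.238 and 0.089). The median was 1.03 in B1, or 1.40 with bounds for genes at 0 counts, and 3.01 in C3. The matrix genes FBN1 and COL3A1 rose by 5.13 ± 0.16 and 1.78 ± 0.36 in B1, and COL5A1 from 1.65 to 53 CPM. Only 2 blood cell markers could be tested, too few for the list test; CORO1A, a leukocyte actin regulator, fell by 6.42 in B1 on the log2 scale, and the list had 1 higher and 1 lower member in each line. All 5 tested antigen presentation genes were higher in both lines, HLA-B by 7.09 ± 0.14 and 6.73 ± 0.15, HLA-C by 7.02 ± 0.15 and 6.91 ± 0.15 and the regulator NLRC5 by 4.04 ± 0.36 and 4.35 ± 0.34, with list adjusted p values of 0.0501 and 0.0785. In B1 the antigen presentation list passed with DESeq2 size factors, with the replicate number as a block, with only the groups compared, and without B1 replicate 1, B1 replicate 2 or C3 replicate 1, with 7 lists each time. For the mean it passed with DESeq2 size factors, without a low-count filter and without control replicate 1. Of 3 cancer-testis genes tested, 2 were higher in B1 and 3 in C3 (medians 1.41, or 2.29 with such bounds, and 5.27; adjusted p = 0.49 and 0.0908).

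Lists close to the known roles of TDRD3 held members called in either direction, in shares that rest on the scaling. Of 17 TDRD3 partners and arginine methylation genes, 8 were higher and 8 lower in B1 and 9 and 7 in C3 (camera adjusted p = 0.924 and 0.824). The deubiquitinase USP9X rose by 1.89 ± 0.038 in B1, while the methyltransferase PRMT6 and the poly(A)-binding PABPC1 fell (-1.50 ± 0.043 and -1.39 ± 0.03). Of 35 R-loop processing genes 16 were higher in each line, with 15 lower in B1 and 16 in C3 (adjusted p = 0.753 and 0.755), and the helicase PIF1, the ribonuclease H2 subunit RNASEH2A and DDX41 fell by 2.12, 1.56 and 1.09 in B1. Of 27 genes of DNA break signalling and repair, 12 were higher and 8 lower in B1 and 11 and 10 in C3 (adjusted p = 0.912 and 0.97). The helicase BRIP1, RAD51C and NBN of the MRN complex were lower in both lines, at -2.33 ± 0.042, -2.19 ± 0.043 and -1.69 ± 0.043 in B1. Among 26 p53 targets 8 were higher and 15 lower in each line (adjusted p = 0.284 and 0.231), with GDF15 and PLK2 at -6.41 ± 0.21 and -3.53 ± 0.099 and GADD45A at 2.65 ± 0.13 in B1. With total-count scaling, the counts of higher and lower members in B1 and C3 were 9 and 5 in each line for the TDRD3 partners, 21 and 12 and then 20 and 12 for R-loop processing, 19 and 8 and then 17 and 6 for DNA break signalling and repair, and 10 and 11 and then 9 and 13 for p53 targets.

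Stress, signalling and metabolic lists gave smaller or split changes. In the interferon list of 32, 10 were higher and 17 lower in B1 and 8 and 18 in C3 (adjusted p = 0.49 and 0.363), with PARP14 and IFITM3 lower (-6.98 ± 0.27 and -3.97 ± 0.07 in B1) and HERC5 higher (4.66 ± 0.15). The NF-kB list of 13 had 6 higher and 5 lower in B1 and 7 and 4 in C3 (adjusted p = 0.964 and 0.81), with ICAM1 and NFKBIA lower (-2.69 ± 0.21 and -2.24 ± 0.059 in B1) and TNFAIP3 higher (2.15 ± 0.21). In B1, 17 of 25 cholesterol synthesis genes were lower and 4 higher, LDLR, MVD and DHCR7 at -1.86 ± 0.057, -1.59 ± 0.064 and -1.72 ± 0.043 (camera adjusted p = 0.0196; adjusted p = 0.28 with an estimated correlation), and in C3 15 were lower and 5 higher (adjusted p = 0.0785). Of 25 G2/M phase genes 17 were lower and 5 higher in B1 (adjusted p = 0.0342; adjusted p = 0.511 with an estimated correlation), and 14 and 4 in C3 (adjusted p = 0.0908), with NDC80, TPX2 and KIF20A lower at -1.24 ± 0.058, -1.57 ± 0.037 and -1.26 ± 0.044 in B1. The G2/M list was not called in B1 with total-count scaling, where 5 lists passed, and 9 of its members were higher and 13 lower in B1 and 11 and 12 in C3. The cholesterol list then had 8 higher and 14 lower in B1 and 9 and 14 in C3. Of 19 NRF2 targets 14 were lower and 5 higher in B1 (adjusted p = 0.0342; adjusted p = 0.389 with an estimated correlation), and 13 and 5 in C3 (adjusted p = 0.0908), with OSGIN1, NQO1 and G6PD lower at -4.92 ± 0.18, -5.18 ± 0.055 and -3.00 ± 0.041 in B1. Calls in B1 that C3 missed are not shown to differ between the lines.

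The remaining lists did not pass the list test against the control in either line. S phase genes (22 tested) had 10 higher and 9 lower members in B1 and 11 and 9 in C3 (adjusted p = 0.912 and 0.918), with DHFR and UHRF1 higher and MCM7 lower. The ATF4 list (26) had 13 higher and 12 lower in B1 and 12 and 10 in C3 (0.879 and 0.755 as adjusted p), with SLC7A5 at -3.06 ± 0.036, NUPR1 at -5.45 ± 0.22 and ATF3 at 2.92 ± 0.16 in B1. Endoplasmic reticulum chaperones (17) had 4 higher and 10 lower in B1 and 7 and 9 in C3 (adjusted p = 0.247 and 0.562), hypoxia and glycolysis genes (24) 12 and 8 in B1 and 14 and 7 in C3 (adjusted p = 0.602 and 0.231), with ADM at 5.31 ± 0.26 in B1. Ribosomal protein genes (40) had 11 higher and 22 lower in B1 and 13 and 22 in C3 (adjusted p = 0.167 and 0.231), with RPL30, RPLP0 and RPS25 lower. Of 9 histone genes 7 were lower in each line (adjusted p = 0.0841 and 0.0908), among them HIST1H2AC and HIST1H2BD. Immediate early genes (22) had 8 higher and 12 lower in each line (adjusted p = 0.461 and 0.483), with JUN at 3.02 ± 0.065 and JUNB at -3.13 ± 0.062 in B1. Of 3 metallothioneins 2 were lower in each line, MT2A at -2.09 ± 0.076 in B1 (adjusted p = 0.284 and 0.231). Under total-count scaling the list median turned positive in B1 for the R-loop, NF-kB, chaperone and ribosomal lists, and in C3 for the G2/M, chaperone and ribosomal lists. More members were then higher than lower among the ribosomal proteins (19 and 15 in each line) and the chaperones (8 and 7 in each line). The counts also moved upward for hypoxia and glycolysis (16 and 5 in each line), S phase (13 and 6 in B1, 13 and 8 in C3) and ATF4 genes (14 and 10, 16 and 9). The signs of median, mean and test disagreed in B1 for the NF-kB, ATF4, DNA break and immediate early lists, and in C3 for the R-loop, S phase, DNA break and immediate early lists. Adjusted over the list alone, counts in both comparisons with the control equalled those over all genes tested.

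**Figure D3:**
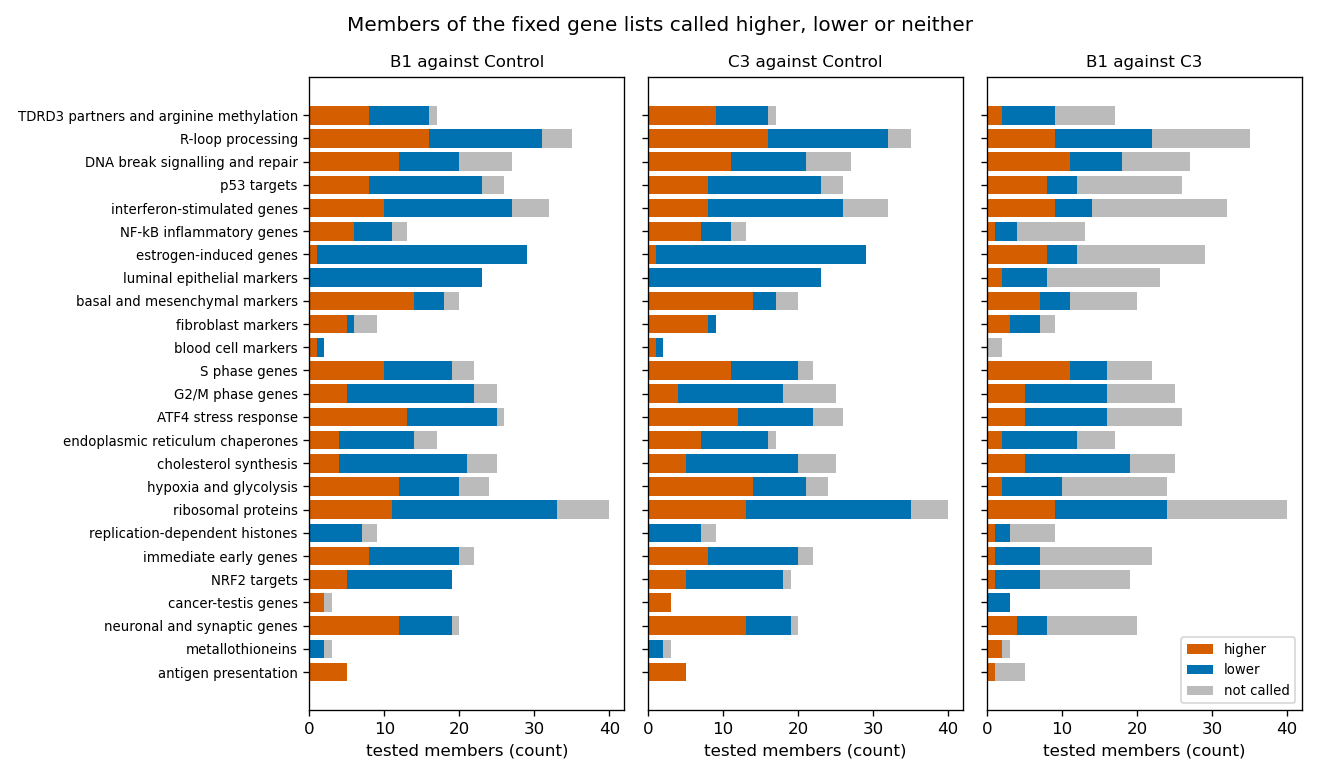
Number of tested members (horizontal axis, count) of each of the 25 lists called higher, called lower or not called in B1 against the control, C3 against the control and B1 against C3. All 23 luminal epithelial markers are called lower in B1 and in C3, and 15 of them are not called between the lines.

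The comparison of B1 with C3 sets the libraries labelled B1 and C3 side by side without the control. The differences were smaller: 3213 genes were higher in B1 and 3313 lower, with 257 and 223 of them by at least 2-fold, against 6516 genes of at least 2-fold between B1 and the control. Higher in B1 were GABRE, a GABA receptor subunit, at 57.3 ± 4.11 against 0.524 ± 0.127 CPM, and STMN2, a neuronal microtubule regulator, at 36.9 ± 2.28 against 0.964 ± 0.0209 CPM. The translation termination factor GSPT2 had 314 counts in B1 and 1 in C3, a ratio of 305 with a counting interval of 54.4 to 12088, and ZNF433 was at least 11.3-fold higher. Lower in B1 were SAGE1, a cancer-testis gene, by at least 86.5-fold, RBP7 (1 count against 315), the meiotic gene HORMAD1 (2 against 264) and NRK (3 against 252). TDRD3 was higher in B1 than in C3 by 0.67 ± 0.14 (adjusted p = 4.66e-05). DHX9 had a log2 difference of -0.092 ± 0.034 (edgeR adjusted p = 0.021), a call that total-count scaling, no low-count filter, DESeq2 and leaving out either B1 library or C3 replicate 1 each ended.

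Between B1 and C3 the list test called 2 lists. Of 17 endoplasmic reticulum chaperones 10 were lower and 2 higher in B1, with XBP1 at -0.62 ± 0.039 and MANF at -0.58 ± 0.043 (camera adjusted p = 0.0162; adjusted p = 0.49 with an estimated correlation). All 3 cancer-testis genes were lower in B1, PRAME at -1.32 ± 0.05 (adjusted p = 0.00284; adjusted p = 0.49 with an estimated correlation). With the replicate number as a block the chaperone list was not called, and with no low-count filter or with 1 CPM in 2 libraries the cancer-testis list was not, which left 1 list each time. Neither list was called without control replicate 1 or without control replicate 2, where 0 lists passed. Cholesterol synthesis, G2/M and NRF2 lists did not pass between the lines (camera adjusted p = 0.0826, 0.0826 and 0.063). The NRF2 list passed there with only the groups compared (4 lists), without B1 replicate 1 (3 lists) and without C3 replicate 1 (4 lists), and the G2/M list without C3 replicate 2 (3 lists). The luminal list also passed with only the groups compared, and the ribosomal list without C3 replicate 1. Adjusted over the list alone, 12 instead of 11 G2/M genes and 10 instead of 8 hypoxia and glycolysis genes were lower in B1, with other counts within 1 of those over all genes tested. For single genes, the log2 difference of NQO1 was -1.22 ± 0.079, that of the glucose transporter SLC2A3 -1.49 ± 0.10 and that of COL3A1 -1.24 ± 0.21, while that of the replication helicase subunit MCM7 was 0.75 ± 0.034. Median, mean and test disagreed in sign for the basal, interferon, estrogen and neuronal lists.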

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

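Of the tests below, those of normalization, of a mixture, of the spread between libraries and of the low counts in the control libraries were chosen after the result was seen, and the others were written before, though after the largest changes had been seen. In 2 cases (a mixture, and an even exchange of reads) the value of the test written first was the one the explanation predicted, and further tests were added after it, 1 for the mixture and 2 for the exchange, with all values given. In another case, loss of TDRD3 as the whole cause, CDKN2A took the place of MTAP after the values of both were seen.

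Results were singled out where B1 and C3 differed by a test of the difference itself (B1 against C3, edgeR for genes and camera for lists). These were 3213 genes higher and 3313 lower in B1, and the medians of the endoplasmic reticulum chaperones (-0.16) and the cancer-testis genes (-2.10) on the log2 scale. Both list calls were made with the preset correlation (camera adjusted p = 0.0162 and 0.00284). With an estimated correlation the camera adjusted p was 0.49 for each. The estimate lay below the preset for the chaperones (-0.0306) and above it for the cancer-testis genes (0.0917). A correlation above the preset therefore did not end the chaperone call, and what ended it was not tested. Log2 differences above 1 in B1 over C3 were found for PTPRD (2.98), FOXE1 (1.06), ZSCAN18 (2.85), GSPT2 (8.25), ZNF433 (3.50), GABRE (6.76) and STMN2 (5.25), where the value of ZNF433 is a lower bound and that of GSPT2 rests on 1 count in C3. Differences below -1 were found for SNPH (-1.25), RBP7 (-8.34), SAGE1 (-6.43), HORMAD1 (-7.09), NRK (-6.43), COL3A1 (-1.24), SLC2A3 (-1.49), NQO1 (-1.22) and PRAME (-1.32), where SAGE1 is a bound and RBP7, HORMAD1 and NRK rest on 1 to 3 counts in B1. Smaller positive differences were those of EMX2OS (0.40), GPR50 (0.40), USP9X (0.14), NBN (0.23), HERC5 (0.67), FBN1 (0.54), COL5A1 (0.63), DHFR (0.25), MCM7 (0.75), UHRF1 (0.12), NDC80 (0.17), NCAM1 (0.16), MT2A (0.36), MT1F (0.64), HLA-B (0.36), TDRD3 (0.67) and CDKN2A (0.24). Smaller negative differences were those of RBP1 (-0.33), FAT3 (-0.61), SLC7A3 (-0.49), PCYT1B (-0.53), CCBE1 (-0.79), PABPC1 (-0.075), RAD51C (-0.23), SNAI2 (-0.46), TPX2 (-0.64), ATF3 (-0.54), SLC7A5 (-0.23), XBP1 (-0.62), MANF (-0.58), LDLR (-0.22), DHCR7 (-0.23), EGLN3 (-0.43), RPLP0 (-0.13), HIST2H2BE (-0.62), JUN (-0.18), NEFL (-0.56), NEFM (-0.94), DHX9 (-0.092) and TOP3B (-0.20). ESRP1 and PKP3 had 0 counts in B1 and 4 in C3, where the floor of 3 counts gave log2 differences of -0.46 and -0.46. These values take the 4 counts in C3 as exact, so they do not bound the difference between the lines. The calls of EMX2OS and JUN were lost in 1 alternative each, those of LDLR, MT2A, PCYT1B and SLC7A3 in 2, MT1F in 3, GPR50, NDC80, RBP1 and UHRF1 in 4, PABPC1 in 5, DHX9 and ESRP1 in 6, NCAM1 in 7 and PKP3 in 8.

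The first pattern is the loss of luminal and estrogen-response transcripts, with calls for most genes, in both lines. The tables argue against normalization as the whole cause, since 37 genes of at least 10 CPM in the control had 0 counts in the 4 other libraries, and against a mixture with 1% or more of control cells, since 11 of 23 luminal markers lay below 1% of the control level in all 4 libraries, although the test written first, over 20 abundant control-enriched transcripts that other cells can express too, gave up to 12.6% of the control level, as a mixture predicts. They also argue against loss of TDRD3 in control cells as the whole cause, given the known deletion of CDKN2A in MCF7: the lowest fold of CDKN2A in any of the 4 libraries over any control library was 80.0, whereas MTAP, the gene named in advance, met its 20-fold bound only within its spread (19.1 to 22.8 between single libraries). Cells of another origin stay open, and could be the source of the 4 libraries. MTAP was at least 20.3-fold over the control mean, but the control libraries held more than the few counts of MTAP and CDKN2A that had been predicted. Of 8 markers known from HEK293 cells, 5 met their bounds (VIM, INA, CDH2, NEFL and NEFM, but not PAX2, NES or NEFH), between the 3 and 6 set for a decision. VIM lay at 607 to 708 CPM against 12.1 in the control. PAX2 was a near miss on which this count rests. It lay at 4.75 to 5.83 CPM in the 4 libraries against 0.0646 in the control, where 5 CPM in all 4 was needed. A change of cell state on loss of TDRD3, as a partial cause, was not tested.

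The second pattern is the set of calls and 2-fold differences between B1 and C3. Too small a spread between libraries as the cause of all of them is argued against by 6 genes with at least 2 CPM in both libraries of a line and at most 3 counts over the other, which is 1 gene past the bound. Segments that differ in copy number could account for some calls, since the share of calls left after a running median of neighbouring genes was taken off was 0.755, between the bounds of 0.5 and 0.8 (4924 of 6526 calls). Few counts stay open as well, with a median of 32.5 counts per library behind the 2-fold differences, between the bounds of 10 and 50. Different effects of the guides, or of TDRD3 levels, were not tested. They cannot be told apart from other differences between the lines, since guide and line go together in these samples.

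The third pattern is a low level, in the control libraries, of transcripts that are abundant in the other 4. Of 47 transcripts with at least 100 CPM in the 4 libraries and at least 20-fold less in the control, 0% lay below 0.3% of the 4-library level (lowest 0.481%, median 1.23%), and in the reverse direction 36.4% of 77 did. Material of the kind in the other libraries may be present in the control libraries. Low expression by the control cells themselves stays open as well, except for the deleted genes named below. The values of 0% and 36.4% come from different cells and from a bound set after the pattern was seen, and decide neither. The tables also argue against an even exchange of reads between all libraries as the whole cause: although the 77 reverse transcripts kept a median of 0.838%, as it predicts, and only 3 of them had 0 counts in all 4 libraries, 29.9% had an upper 95% counting limit below 0.24%, the floor an equal exchange would set. CDKN2A, at 0.929% to 1.10% of the 4-library level in the control, lay near the median of 1.23%, and MTAP, at 4.68% to 4.93%, above it. The control libraries held 42 and 32 counts of CDKN2A and 85 and 75 of MTAP. Given the known deletion of both genes in MCF7, these counts argue against expression by MCF7 cells as their source, less firmly for MTAP. Its level lay above that of CDKN2A and above the median, and the source of that excess was not tested. The argument holds for these genes only.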

How the results depend on the processing

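No called named gene changed direction under the alternatives run. The balance of calls between B1 and C3 (3213 higher, 3313 lower) turned to 3509 and 2971 with total-count scaling, 3227 and 3210 with 1 CPM in 2 libraries and 3290 and 3285 with only the groups compared. Under total-count scaling some list medians changed sign (in B1 R-loop -0.023 to 0.22, NF-kB -0.13 to 0.10, chaperones -0.22 to 0.016 and ribosomal -0.19 to 0.053; in C3 G2/M -0.19 to 0.025, chaperones -0.20 to 0.019 and ribosomal -0.16 to 0.052; in the mean chaperones -0.14 to 0.091 and ribosomal -0.20 to 0.028; between B1 and C3 basal -0.0036 to 0.018). Of values under alternatives, 189 for the counts, lists, correlation and TDRD3 kept their side and 34 moved, and for the other named genes 4273 kept their call, 61 lost it and 6 gained it, all of the last 2 kinds between B1 and C3. TDRD3 was called lower in both lines throughout.

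A minimum fold of 1.5 left 4264 higher and 3861 lower genes in B1, 4325 and 3878 in C3, 4323 and 3924 in the mean, and 251 and 184 between B1 and C3, by its construction. DESeq2 called 2119 and 2149 genes between B1 and C3. The correlation of log2 fold changes (0.976) moved by more than its SD over single-library versions, 0.000148, to 0.9757 with total-count scaling, 0.935 without a filter, 0.978 with 1 CPM in 2 libraries and 0.948 with DESeq2, and ranged from 0.969 to 0.976 without single libraries.

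List calls changed with the settings. With an estimated correlation 0 lists passed in each of the 4 comparisons (camera; 6, 3, 4 and 2 with the preset), with 4, 3, 3 and 2 at an unadjusted p under 0.05. In B1 the estimate lay below the preset of 0.01 for luminal (-0.034), estrogen-induced (-0.00045), basal (-0.040) and cholesterol genes (-0.0042). A correlation above the preset therefore did not end the calls of these lists in B1. The estimate in B1 lay above the preset for G2/M (0.121) and NRF2 genes (0.0368). Below the preset were also luminal and basal genes in C3 (0.0037 and -0.034) and in the mean (-0.0093 and -0.038). In the mean this held for cholesterol genes too (-0.0015). Estrogen-induced genes lay above it in C3 (0.0439) and in the mean (0.025). Where the estimate lay below the preset, a lost call does not show that correlation among the members weakened the list. For the mean, 7 passed with DESeq2 size factors and 8 without a filter, and 3 to 7 without single libraries. Between B1 and C3, 1 passed without a filter and with 1 CPM in 2 libraries, 4 with only the groups compared, and 0 to 4 without single libraries. The cause of these changes in list calls was otherwise not tested.

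Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.023, -0.00045 and 0.0014. With the number as a block, 1 list passed between B1 and C3, and no count of genes moved by over 1.5 times. Depth limits the low genes, where 1 count is 0.0535 to 0.0648 CPM.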

Other observations

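Of the tests in this part, the comparison of zinc finger with other genes was chosen after the result was seen, and the test of neighbouring genes was written before it. Zinc finger genes with a ZNF symbol, mostly transcriptional repressors with many near-identical copies, stood out between B1 and C3. Of 476 tested, 26 differed by at least 2-fold, 24 of them higher in B1 and 2 lower. That is 5.46% against 3.1% of the 14648 other genes (odds ratio 1.81, 95% interval 1.15 to 2.72, Fisher's exact test, two-sided, p = 0.00724, adjusted over the pair of tests 0.0145). The odds ratio lay between the bounds of 1.5 and 2 set for a decision, so an excess of this family stays open. Fisher's test takes genes as independent, so its p is too small and its interval too narrow if neighbouring genes moved together. A hypothesis is that runs of neighbouring zinc finger genes moved together: 18 of the 26 had a called neighbour of the same sign, against 13.3 expected in permuted order (one-sided permutation test, 10000 permutations, p = 0.0447, adjusted 0.0447). A neighbour here is the nearest tested ZNF gene in order along the chromosome, at any distance. Other genes between them were left out. Neighbouring genes of this family may have moved together, but the permutation p lies close to its threshold, reads shared between copies were not ruled out, and differences in copy number between the lines were left open above.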
